A study of Rattus norvegicus with 9 samples.

How the data were processed

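Total RNA of gastrocnemius muscle from male Wistar rats was measured on Affymetrix rat genome expression arrays, with 1 array per animal, 3 animals per group and 9 arrays in all. The groups received vehicle (propylene glycol), dexamethasone, or dexamethasone together with testosterone from implanted osmotic pumps for 7 days. Dexamethasone was given at 0.7 mg/kg/day. The sample labels give the testosterone dose as 28 mg/kg/day and the series design as 20 mg/kg/day, and which is right was not settled here. Per the labels' protocols, a small piece of muscle was homogenized, RNA was extracted with phenol and chloroform and cleaned on columns, and biotin-labelled target was made by the standard Affymetrix protocol. The part of the muscle that was taken, the dates of hybridisation and the signal algorithm are not given in the sources used here.

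The deposited values are linear intensities, a single signal for each of 31099 probe sets on each array. In 5 arrays the mean signal, without the lowest and highest 2% of probe sets, was 500. In the other 4 arrays (vehicle replicates 1 and 3, dexamethasone replicate 1, dexamethasone plus testosterone replicate 1) it lay between 113.2 and 206.7, so these were not brought to a common scale before deposit. Array medians on the log2 scale spanned 1.82. The rule fixed in advance called for quantile normalization where that span exceeded 0.1.

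Of the probe sets, 57 Affymetrix controls were left out. The log2 of the intensity plus a pseudocount of 16 was quantile normalized with limma 3.58.1 in R 4.3.3. A fold change is thus on the log2(intensity + 16) scale, which understates the change of dim probe sets. Probe sets with a mean below the 40th percentile were left out, and 18625 were tested. Each was fitted by limma (lmFit and eBayes) with a mean per group over all 9 arrays, so that the groups share a single estimate of the spread. Benjamini-Hochberg adjustment was applied within each comparison, with a threshold of 0.05. The number of arrays limits the precision. Every p-value of a probe set in the text is from this limma test unless another is named, and all standard errors are those of the same fit.

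Gene symbols came from the platform annotation and were updated through gene IDs to the rat annotation GRCr8. Of the 31042 probe sets other than controls, 20826 had 1 symbol, 436 had several and 9780 had none here; 20758 symbols were found by gene ID. No gene was named from a probe set with several symbols. A gene was represented by its probe set with the highest mean over the 9 arrays, which gave 10428 genes.

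The tests, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where the closing section says otherwise. By that rule, the text names 14 genes of glucocorticoid or androgen action whatever their result, of which 1 is not reported here. It also names, for each comparison, the 8 largest rises and the 8 largest falls among genes past the threshold whose arrays do not overlap between the groups, and up to 4 members of each list past the threshold. Where fewer than 5 genes passed in a direction, the 5 with the lowest unadjusted p are given as values that did not pass. Members of lists quoted with an adjusted p above the threshold are examples chosen after their values were seen.

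Lists of genes for muscle atrophy, hormone action, metabolism, fibre type and matrix, and markers of other cell types, 29 in all, were tested with camera in limma at a preset correlation between genes of 0.01. Camera compares a list with all other genes. Beside it stand camera with the correlation estimated from the data and fry, whose adjusted p is given as fry. The neutrophil list had fewer than 3 measured members and was not tested. Benjamini-Hochberg adjustment ran over the 28 tested lists in each comparison, and "adjusted over the list alone" means adjustment of the limma p over the members of that list only.

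Comparisons of dexamethasone with vehicle and of the combination with dexamethasone share the dexamethasone arrays. Their covariance was therefore set against 100 simulated data sets with unchanged groups and noise drawn independently for each probe set. The noise had the same spread in all groups. In a cross-fitted estimate, each dexamethasone array in turn was kept out of the choice of probe sets and used alone to measure how much of the effect testosterone reversed. The vehicle arrays still entered both the choice and the measurement. The count of probe sets that moved back on the array kept out was added after the results had been seen.

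The deposited scaling and the signals of the poly-A spikes, added to the RNA before labelling, split the arrays into 3 technical batches. This split was made after the values had been seen and uses no muscle gene. Batch A holds the 4 arrays without common scaling. Batch B holds vehicle replicate 2, dexamethasone replicate 2 and dexamethasone plus testosterone replicate 2. Batch C holds dexamethasone replicate 3 and dexamethasone plus testosterone replicate 3, whose poly-A spike signals were 0.958 and 2.05 times the trimmed mean, against 8.19 to 68.3 times in the other arrays. Results were repeated with batch as a block, within each batch and without batch C.

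The limma step was tested on simulated data for the comparison of dexamethasone with vehicle over 18625 probe sets, with 1.07% of them changed and the measured spread, in 10 draws. It recovered 20.8% of 2-fold, 71.6% of 4-fold and 90.5% of 8-fold changes, and 4.7% of its calls were false. For the cross-fitted share over the same number of probe sets, true shares of 0, 0.5 and 1 gave estimates of 0.00486, 0.493 and 0.979. Each was a single draw with 10.7% of probe sets changed by 4-fold. All simulated noise was independent between probe sets, so deviations that probe sets of a real array share are not covered. With no effect, camera called a mean of 0.25 of 84 tests of lists; this simulation had no correlation between genes.

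Alternatives covered the normalization, centring, filter, pseudocount, variance model, arrays in the fit, array weights, the replicate number as a block, each array left out in turn, the probe set per gene and the size of change. Figures were drawn with matplotlib 3.10.9.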

Results

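Gene expression in the gastrocnemius, a calf muscle of mixed fibre type, was measured after 7 days of hormone infusion in male rats of 250 g. The 3 groups, each of 3 animals, received vehicle, the synthetic glucocorticoid dexamethasone, or dexamethasone with testosterone. The questions were which transcripts the glucocorticoid changes in muscle and what testosterone does to those changes. Median deposited signals ran from 25.8 to 132.1 per array. After normalization, the arrays correlated with one another at 0.876 to 0.973 across probe sets.

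Dexamethasone replicate 3 and dexamethasone plus testosterone replicate 3, which form technical batch C, stood apart from the other arrays in RNA quality measures. The signal at the 3' end of Gapdh was 4.94 and 6.22 times that at its 5' end in these 2 arrays, against 1.06 to 1.17 times in the other 7. The first principal component, with 35.2% of the variance, placed them at 60.6 and 68.1, and the others between -40.6 and 20.7. Batch C holds no vehicle array, so the comparisons with vehicle have within-batch values for batches A and B only.

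Dexamethasone changed muscle transcripts of glucocorticoid signalling, extracellular matrix and single enzymes of amino acid metabolism. In the dexamethasone group 196 of 18625 probe sets differed from vehicle (limma, adjusted p under the threshold), 106 higher in 81 genes and 90 lower in 67 genes. The largest rise was in Arrdc2, which encodes an arrestin-domain protein. It was 25.6-fold higher (log2 change 4.68 ± 0.55 SE, n = 3 per group, adjusted p = 0.0166). The largest fall was in Nmrk2, a muscle nicotinamide riboside kinase, which was 30.4-fold lower (log2 change -4.93 ± 0.64 SE, adjusted p = 0.0206).

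Known target genes of the glucocorticoid receptor rose as a group. Of 27 measured members, 16 rose, 0 fell and 11 did not pass; adjusted over the list alone, 19 rose. The median log2 change was 1.48 (camera adjusted p = 3.7e-14, fry 0.00024, and adjusted p = 0.029 with an estimated correlation). With batch as a block and an estimated correlation the adjusted p was 0.19. Metallothionein Mt2A rose by 3.58 ± 0.43 on the log2 scale, Ddit4, an inhibitor of mTORC1 signalling, by 3.25 ± 0.42, and the transcription factor gene Cebpd by 3.14 ± 0.33, with adjusted p of 0.0166, 0.0206 and 0.0166. The clock gene Per1 rose by 1.97 ± 0.22 (adjusted p = 0.0166), the transcription factor gene Klf15 by 1.48 ± 0.24 (adjusted p = 0.0324) and Nfkbia, an inhibitor of NF-kB, by 1.46 ± 0.28 (adjusted p = 0.0476). The list median was 1.8 within batch A and 1.57 within batch B.

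**Figure D1:**
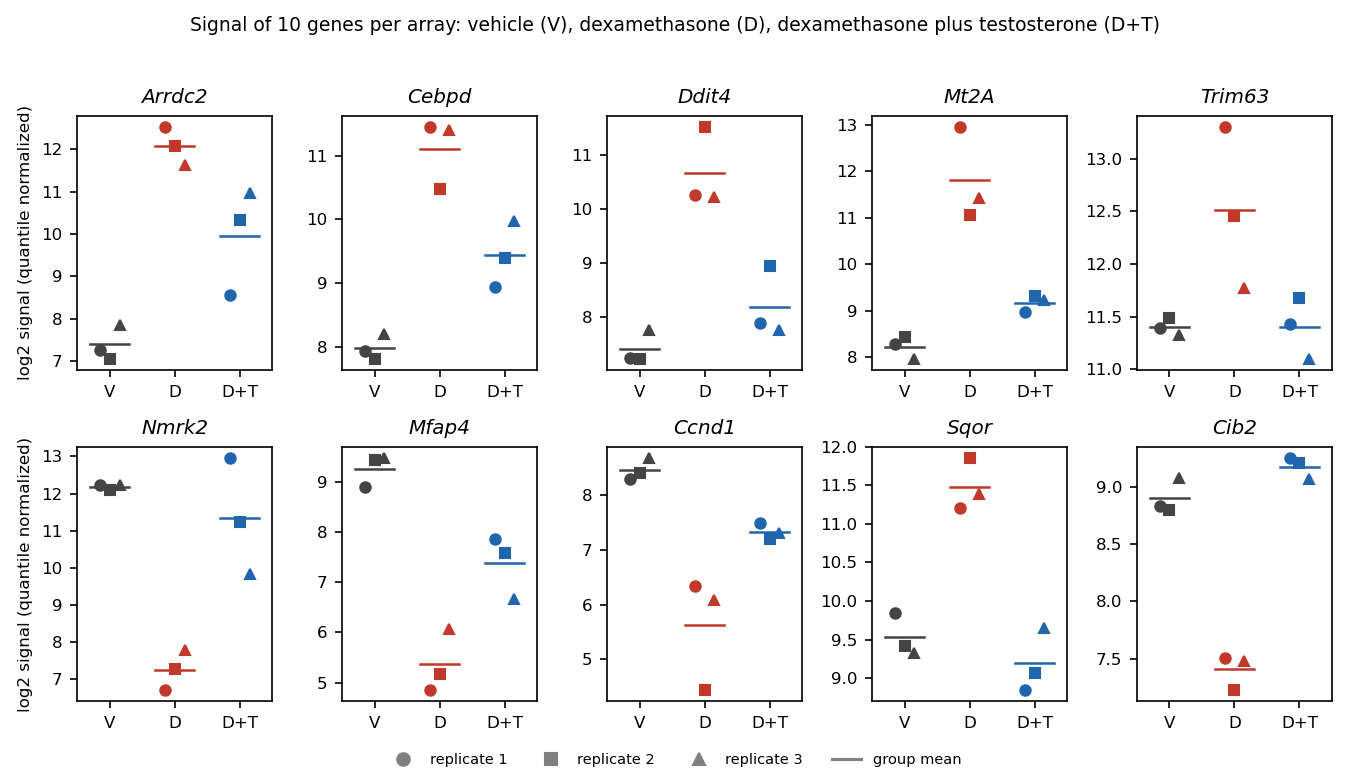
Quantile-normalized log2 signal of 10 genes in each of the 9 arrays, by group, with a symbol per replicate and a line at the group mean. In dexamethasone, Arrdc2 lay between 11.63 and 12.52 and Nmrk2 between 6.71 and 7.78, while in vehicle they lay between 7.06 and 7.86 and between 12.09 and 12.22.

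Enzymes of amino acid metabolism were among the largest rises. Mitochondrial arginase Arg2 rose by 4.28 ± 0.67 on the log2 scale (adjusted p = 0.0324), glycine methyltransferase Gnmt by 3.46 ± 0.44 (adjusted p = 0.0206) and proline dehydrogenase Prodh by 3.38 ± 0.47 (adjusted p = 0.0213). Chac1, which breaks down glutathione, rose by 3.49 ± 0.46 (adjusted p = 0.0206), and glutamine synthetase Glul by 1.47 ± 0.21 (adjusted p = 0.022). The list of amino acid metabolism as a whole did not pass (25 genes, median 0.15, adjusted p = 0.17). Ryr3, a calcium release channel, rose by 4.47 ± 0.86 (adjusted p = 0.0497), with log2 changes of 1.84 in batch A and 6.87 in batch B.

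Extracellular matrix genes were lower in all 3 dexamethasone arrays. Of 43 measured members, 4 fell (Col5a3, Fn1, Col6a2 and Lamb1), 0 rose and 39 did not pass; adjusted over the list alone, 29 fell. The list fell by a median of 1.53 on the log2 scale (camera adjusted p = 1.3e-19; fry 0.025), but adjusted p = 0.29 with an estimated correlation. Col5a3 fell by 2.87 ± 0.46 (adjusted p = 0.0324), fibronectin Fn1 by 2.24 ± 0.37 (adjusted p = 0.0324), Col6a2 by 1.98 ± 0.34 (adjusted p = 0.0359) and laminin Lamb1 by 1.77 ± 0.28 (adjusted p = 0.0324). The main fibrillar collagen genes Col3a1 and Col1a1 had log2 changes of -3 ± 0.71 and -2.98 ± 0.94 and did not pass (adjusted p = 0.0857 and 0.169). Relative to the vehicle mean, the list medians were -2.19, -1.35 and -0.84 in dexamethasone replicates 1, 2 and 3.

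Markers of fibroblasts, the cells that make much of this matrix, moved the same way. Mfap5 fell by 1.75 ± 0.29 (adjusted p = 0.0338) and was the 1 of 13 markers that passed; adjusted over the list alone, 9 fell. The list median was -1.31 (camera adjusted p = 3.5e-08; adjusted p = 0.35 with an estimated correlation; fry 0.051), and -0.77 without dexamethasone replicate 1. Relative to the vehicle mean it was -1.96, -1.2 and -0.73 in dexamethasone replicates 1, 2 and 3. The matrix list holds 5 of these markers, and the other 8 had a median of -0.91, all below 0. Mfap4, a microfibril protein gene, fell by 3.9 ± 0.39 (adjusted p = 0.0161) and the matricellular gene Smoc2 fell as well (-2.98 ± 0.49, adjusted p = 0.0324).

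The remaining large falls were in Nrep, which fell by 3.16 ± 0.51 on the log2 scale, the imprinted gene Mest, by 2.89 ± 0.42, and carbonic anhydrase Car4, by 2.64 ± 0.45. Their adjusted p were 0.0324, 0.0244 and 0.0359. Cyclin D1, Ccnd1, fell by 2.85 ± 0.43 (adjusted p = 0.029) and was the 1 of 22 cell cycle genes that passed; adjusted over the list alone, 7 fell. The cell cycle list had a median of -0.45 (camera adjusted p = 0.002; adjusted p = 0.26 with an estimated correlation), and did not pass with a filter at the 60th percentile (-0.28, adjusted p = 0.11). The chemokine gene Ccl2 fell by 1.7 ± 0.25 (adjusted p = 0.0244) as did muscle fructose bisphosphatase Fbp2 (-1.22 ± 0.21, adjusted p = 0.0367), while the antiviral gene Oas1a rose by 2.13 ± 0.4 (adjusted p = 0.0464).

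Genes of protein breakdown shifted upward by less. The 36 proteasome subunits had a median log2 change of 0.39 (camera adjusted p = 9.6e-06; adjusted p = 0.35 with an estimated correlation). None passed singly, but adjusted over the list alone 11 rose and 1 fell. The atrophy-associated list had a median of 0.34 (23 genes, camera adjusted p = 0.0054; adjusted p = 0.35 with an estimated correlation). Its 2 members that rose were Mt2A, which binds metals, and Eif4ebp1, a repressor of cap-dependent translation (2.47 ± 0.38, adjusted p = 0.0306); adjusted over the list alone, 6 rose. The muscle ubiquitin ligase genes Trim63 and Fbxo32 had log2 changes of 1.11 ± 0.35 and 1.24 ± 0.62 and did not pass (adjusted p = 0.168 and 0.384). Among the alternative settings, Trim63 passed in 2 of 23 (lowest adjusted p = 0.0411) and Fbxo32 in 2 of 22 (lowest adjusted p = 0.0205). Trim63 was higher in each of the 3 dexamethasone arrays than in any vehicle array, with log2 changes of 1.95 in batch A and 0.97 in batch B. With batch as a block its adjusted p was 0.0674. Fbxo32 had log2 changes of 2.03 in batch A and 2.2 in batch B. Its signal was 8.16, 8.14 and 5.61 in dexamethasone replicates 1, 2 and 3, against 5.94 to 6.26 in vehicle.

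Autophagy and lysosome genes included 3 that rose of 29, and adjusted over the list alone 6 rose. These 3 were cathepsin Ctsl (2.13 ± 0.28, adjusted p = 0.0206), Map1lc3a (1.28 ± 0.21, adjusted p = 0.0324) and Atg4a (1.09 ± 0.21, adjusted p = 0.0471). The list median was 0.22 (camera adjusted p = 0.026; adjusted p = 0.36 with an estimated correlation), and it did not pass without dexamethasone replicate 1 (adjusted p = 0.097). Fatty acid oxidation genes had a median of 0.3 (35 genes, camera adjusted p = 0.007; adjusted p = 0.54 with an estimated correlation), and 1 rose, the pyruvate dehydrogenase kinase gene Pdk4 (1.82 ± 0.33, adjusted p = 0.04); adjusted over the list alone, 2 rose. That list did not pass without vehicle replicate 3 (median 0.23, adjusted p = 0.061) or dexamethasone replicate 2 (median 0.16, adjusted p = 0.63).

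Insulin-like growth factor, mTOR and myostatin signalling did not pass as a list (39 genes, median 0.06, adjusted p = 0.78). Besides Ddit4, Eif4ebp1 and Sesn1, Igfbp3 rose (1.64 ± 0.24, adjusted p = 0.0227), and Igfbp5 and Irs1 fell (-2.52 ± 0.46, adjusted p = 0.0415, and -1.43 ± 0.26, adjusted p = 0.0396); adjusted over the list alone, 4 rose and 4 fell. Of the androgen and polyamine list (20 genes, median -0.27, adjusted p = 0.41), Arg2 and the zinc transporter gene Slc30a2 rose (Slc30a2: 1.61 ± 0.21, adjusted p = 0.0206). Adjusted over the list alone, 4 rose and 2 fell.

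Of the other genes named in advance, the log2 changes were -0.85 ± 0.35 for Igf1 (adjusted p = 0.287), -0.15 ± 0.65 for myostatin, Mstn (adjusted p = 0.938), and 0.68 ± 1.01 for Foxo1 (adjusted p = 0.795). Signals in dexamethasone replicates 1, 2 and 3 were 8.72, 9.18 and 6.84 for Mstn and 6.27, 10.17 and 6.45 for Foxo1. Over the alternative settings their changes ran from -0.62 to 0.55 (Mstn) and from -0.59 to 1.36 (Foxo1). For the further genes the values follow. Log2 changes were -0.56 ± 0.25 for ornithine decarboxylase Odc1 (adjusted p = 0.324), -0.89 ± 0.32 for Amd1 (adjusted p = 0.226) and -0.37 ± 0.23 for the glucocorticoid receptor gene Nr3c1 (adjusted p = 0.488). Ppargc1a changed by 0.01 ± 0.23 (adjusted p = 0.991) and Rcan2 by -0.48 ± 0.27 (adjusted p = 0.435). Fkbp5 had a log2 change of 2.08 ± 0.57 (adjusted p = 0.12), while its other probe set passed at 3.05. Further probe sets of Col6a2, Igfbp3, Klf15 and Pdk4 had the same sign as the one named but did not pass (-0.28, 0.72, 0.84 and 0.95). The 2 others of Igf1, which did not pass, stood at -1.97 and -1.19. Some further probe sets of Ccnd1, Glul and Igfbp5 also did not pass, all with the same sign, and that of Ppargc1a had the opposite sign (-0.12).

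With batch as a block 179 probe sets passed (82 higher and 97 lower), 107 of them among the 196. All 196 moved the same way within batches A and B, which their choice from these arrays largely brings about. Of 36 named genes past the threshold, 23 also passed with the block, and the others had adjusted p up to 0.083. Without batch C 444 passed. Leaving out a single array gave 2 calls (vehicle replicate 1), 1 (vehicle replicate 2 or 3), 3 (dexamethasone replicate 1) or 10 (dexamethasone replicate 2). Without dexamethasone replicate 3 there were 333, and without combination replicate 1, 2 or 3 there were 193, 49 or 253. In each such fit all 196 kept their direction and an unadjusted p under 0.05, which their choice from these arrays largely brings about.

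Adding testosterone to dexamethasone lowered glucocorticoid target genes as a group, while calls of single genes were few and depended on the settings. Compared with dexamethasone alone, 21 probe sets passed, 13 higher in 9 genes and 8 lower in 7 genes. That count was 0 with no filter or without batch C, and 149 with an intensity trend and robust variance. The largest fall was in Fah, an enzyme of tyrosine breakdown, which was 7-fold lower (log2 change -2.81 ± 0.4 SE, n = 3 per group, adjusted p = 0.049). Sqor, a mitochondrial sulfide oxidase, fell by 2.29 ± 0.27 on the log2 scale (adjusted p = 0.036). The largest rise was in the predicted gene LOC100909396, 5.7-fold higher (log2 change 2.51 ± 0.25, adjusted p = 0.0179).

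Other genes that fell were the phosphatase gene Ctdspl (-2.24 ± 0.32, adjusted p = 0.0488), the phospholipase gene Pla2g12a (-2.14 ± 0.26, adjusted p = 0.036) and Slc30a2 (-1.61 ± 0.21, adjusted p = 0.036). The potassium channel gene Kcnq5 fell by 1.6 ± 0.21 (adjusted p = 0.0432) and the sialyltransferase gene St3gal2 by 1.52 ± 0.2 (adjusted p = 0.0432). Genes that rose were Gpm6b (2.31 ± 0.3, adjusted p = 0.036), the amino acid decarboxylase gene Gadl1 (2.27 ± 0.29, adjusted p = 0.036) and Inhca (2.27 ± 0.31, adjusted p = 0.0472). So did the predicted gene LOC102548331 (2.1 ± 0.21, adjusted p = 0.0179), Cib2 (1.77 ± 0.18, adjusted p = 0.0179), Paip1 (1.64 ± 0.2, adjusted p = 0.036) and Tfdp1, a partner of E2F factors (1.4 ± 0.19, adjusted p = 0.0472). Further probe sets of Ctdspl, Gpm6b, Inhca, Paip1, Slc30a2 and St3gal2 had the same sign and did not pass. The 2 others of Kcnq5 stood at -0.02 and 0.12.

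Glucocorticoid receptor target genes were lower under both hormones than under dexamethasone alone. Their median log2 change was -0.97 (27 genes, camera adjusted p = 1.7e-14, fry 0.00089, and adjusted p = 0.026 with an estimated correlation; 0.21 when batch was also a block). None passed singly, and adjusted over the list alone 19 fell. The median was -1.21 in batch A, -0.92 in batch B and -0.67 in batch C. Ddit4 had a log2 change of -2.47 ± 0.42 (adjusted p = 0.0808), with -2.38, -2.57 and -2.47 in batches A, B and C, and Mt2A one of -2.64 ± 0.43 (adjusted p = 0.0761).

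**Figure D2:**
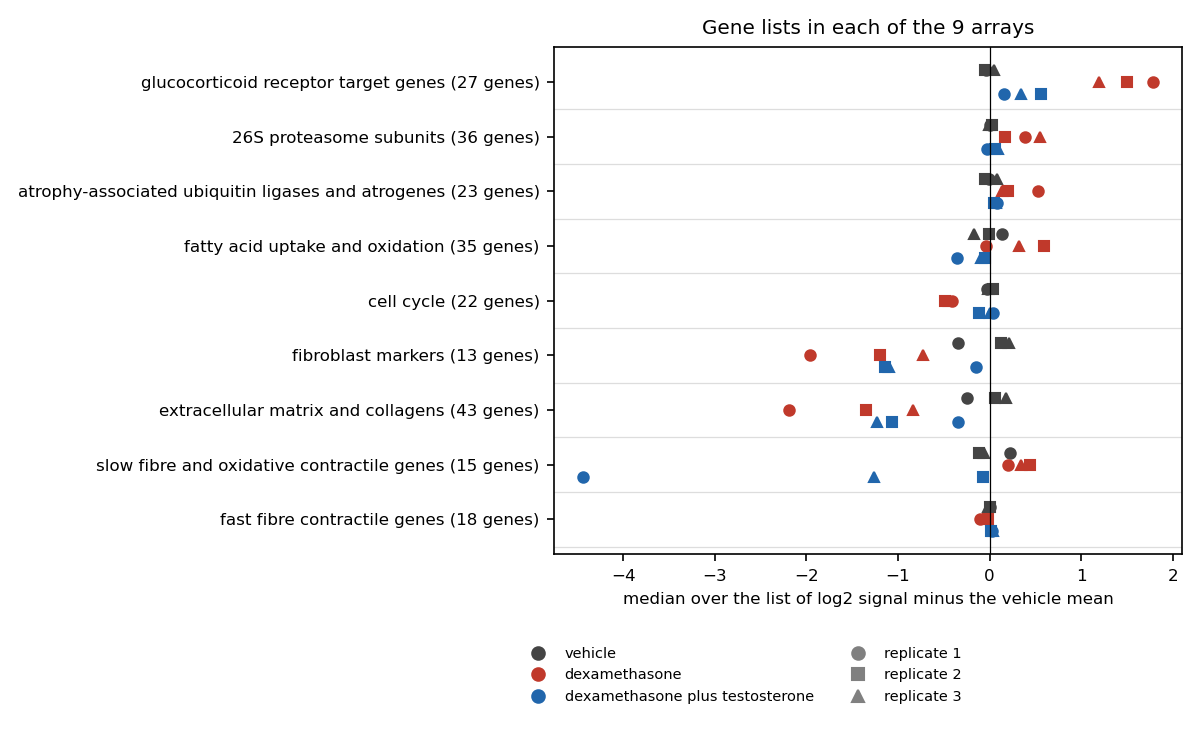
Median over each gene list of the log2 signal minus the vehicle mean, in each of the 9 arrays, with a colour per group and a symbol per replicate. Glucocorticoid receptor targets lay at 1.2 to 1.79 in dexamethasone and at 0.16 to 0.56 in dexamethasone plus testosterone, while slow fibre genes reached -4.44 in a single array.

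Several other lists passed by camera at the preset correlation, with signs opposite to their change with dexamethasone. The comparisons share the dexamethasone arrays, so opposite signs arise in part without any effect of testosterone. Fatty acid oxidation genes had a median of -0.46 (35 genes, adjusted p = 5.9e-08; adjusted p = 0.36 with an estimated correlation). Adjusted over the list alone, 9 fell and 1 rose, among them Acadl (-1.12 ± 0.23) and Cpt1b (-0.99 ± 0.19). Proteasome subunits had a median of -0.33 (36 genes, adjusted p = 1.5e-07; adjusted p = 0.36 with an estimated correlation), with 5 that fell over the list alone. Atrophy-associated genes had a median of -0.23 (adjusted p = 0.0066; adjusted p = 0.36 with an estimated correlation), with 2 that fell over the list alone, and the list did not pass without dexamethasone replicate 1 (adjusted p = 0.065). Cell cycle genes had a median of 0.5 (adjusted p = 0.0036; adjusted p = 0.31 with an estimated correlation), and 2 rose over the list alone; with a filter at the 60th percentile the list did not pass (0.64, adjusted p = 0.11).

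Extracellular matrix genes had a median of 0.55 (43 genes, camera adjusted p = 9.7e-06; adjusted p = 0.44 with an estimated correlation; fry 0.32), and 0 passed over the list alone. The batches differed in it, with 1.81 in batch A, 0.53 in batch B and -0.21 in batch C. The median was 0.33 without dexamethasone replicate 1 (adjusted p = 0.037) and 0.84 without dexamethasone replicate 3. Fibroblast markers had a median of 0.77 (adjusted p = 0.0036; adjusted p = 0.5 with an estimated correlation; 1 rose over the list alone), with 1.95, 0.14 and -0.44 in batches A, B and C. That list did not pass without dexamethasone replicate 1 (median 0.26) or without combination replicate 1 (median 0.65), with camera adjusted p = 0.15 each. The 8 markers that the matrix list does not hold had a median of 0.34, with 1 below 0.

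Slow fibre contractile genes were lower in the combination group, most strongly in a single animal. The median log2 change from dexamethasone was -2.32 (15 genes, camera adjusted p = 2.9e-08; adjusted p = 0.36 with an estimated correlation; fry 0.096), and 6 fell over the list alone. In dexamethasone plus testosterone replicate 1 the slow myosin gene Myh7 stood at 8.74 on the log2 scale, against 14.47 to 14.96 in the vehicle and dexamethasone arrays, and was 58.8-fold below the vehicle mean. Relative to the vehicle mean, the list median was -4.44 in replicate 1, -0.07 in replicate 2 and -1.26 in replicate 3. Without replicate 1 the median change was -0.86 (camera adjusted p = 8.9e-10 at the preset correlation). An estimated correlation was not run in that setting. Slow fibre genes moved together within an array, which the preset correlation may understate. Fast fibre genes did not pass by camera (18 genes, median 0.08, adjusted p = 0.08) but did by fry (adjusted p = 0.00089).

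**Figure D3:**
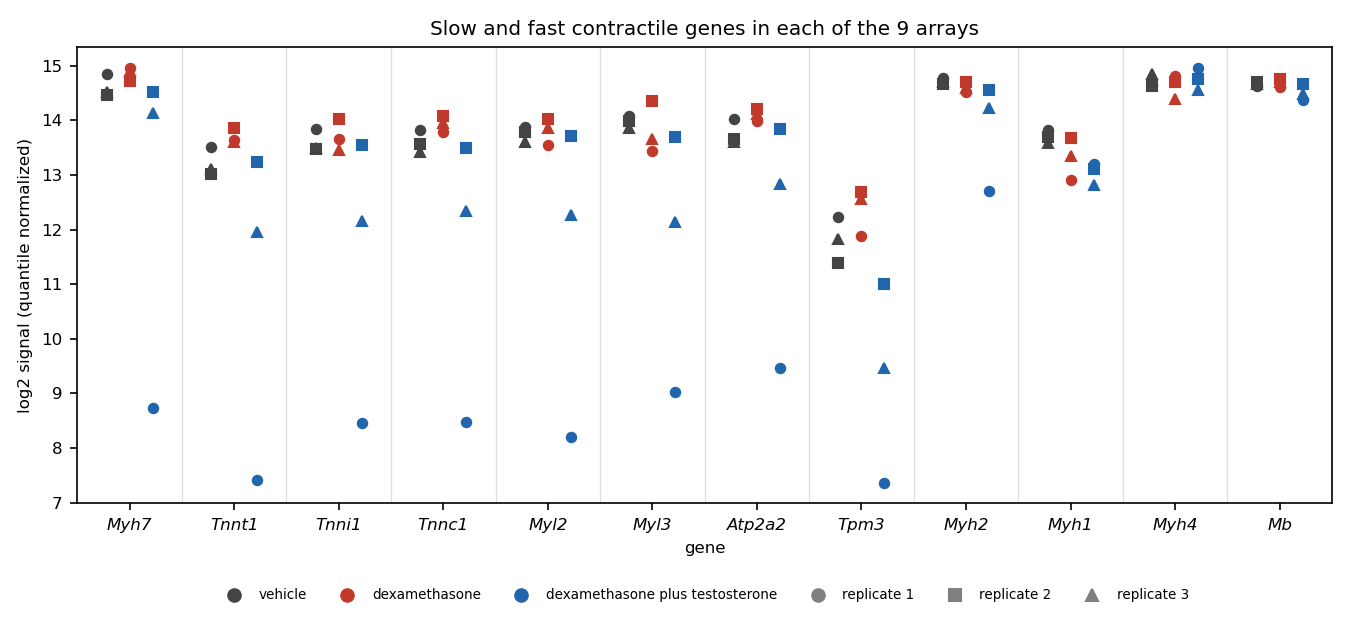
Quantile-normalized log2 signal of slow contractile genes, myoglobin (Mb) and the fast or intermediate myosin genes Myh2, Myh1 and Myh4 in each of the 9 arrays. In dexamethasone plus testosterone replicate 1, Myh7 was at 8.74 and Tnnt1 at 7.42, while Myh4 was at 14.95.

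Of the genes named in advance, Trim63 had a log2 change of -1.11 ± 0.35 (adjusted p = 0.286) and Fbxo32 one of -1.04 ± 0.62 (adjusted p = 0.606). Within batches A, B and C Fbxo32 stood at -2.35, -1.29 and 0.52. Klf15 had a log2 change of -0.93 ± 0.24 (adjusted p = 0.182) and Fkbp5 one of -0.65 ± 0.57 (adjusted p = 0.752). The other probe set of Fkbp5 stood at -1.66 and did not pass. The polyamine gene Amd1 stood at 1.23 ± 0.32 (adjusted p = 0.188) and Odc1 at -0.08 ± 0.25 (adjusted p = 0.949). Igf1 stood at 0.6 ± 0.35 (adjusted p = 0.601), Mstn at -0.09 ± 0.65 (adjusted p = 0.979) and Foxo1 at -0.78 ± 1.01 (adjusted p = 0.858). Over the alternative settings Mstn ran from -0.8 to 0.45 and Foxo1 from -1.46 to 0.49. Nr3c1, Ppargc1a and Rcan2 stood at 0.39 ± 0.23, 0.37 ± 0.23 and 0.16 ± 0.27 (adjusted p = 0.607, 0.637 and 0.898). The other probe sets of Nr3c1 and Ppargc1a had the opposite sign (-0.06 and -0.16).

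With batch as a block 22 probe sets passed, 12 of them among the 21. All 21 moved the same way within batches A, B and C, which their choice from these arrays largely brings about. Without batch C, and when only the 2 groups were fitted, 0 passed. Leaving out dexamethasone replicate 3 gave 68 calls, vehicle replicate 1 gave 5, vehicle replicate 2 gave 1 and any other array 0. All 21 kept their direction and an unadjusted p under 0.05 in each such fit, which their choice likewise largely brings about.

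Probe sets changed by dexamethasone moved back towards vehicle in the combination group, by a share that differed between arrays. The move was read on a dexamethasone array that did not choose the probe sets. With replicates 1, 2 and 3 held out, 3 of 3, 10 of 10 and 262 of 333 moved back. The reference is 50% with no effect of testosterone and no difference between batches. The held-out array is of 1 batch and the combination arrays are of 3, so a batch difference can enter these counts. Probe sets are not independent, so no p is given. On the arrays that chose them, 106 of the 106 higher probe sets moved down and 89 of the 90 lower ones moved up, which the choice alone brings about in part. Of the probe sets called for testosterone, 6 of the 8 that it lowered, with 0.0455 expected from independent lists, were higher with dexamethasone. Likewise 12 of the 13 that it raised were lower with dexamethasone, with 0.0628 expected. Both comparisons use the same dexamethasone arrays, so the overlap expected from independent lists is too low a reference.

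Across the probe sets tested, the covariance of the 2 sets of log2 changes was -0.17, against -0.07 in simulated unchanged groups that shared the same arrays (range -0.08 to -0.07), a difference of -0.10. The correlation, across probe sets that are not independent replicates, was -0.70 against a simulated -0.50. The simulated noise was independent between probe sets, so these references leave out deviations that probe sets of an array share. They also gave all groups the same spread, while the dexamethasone arrays correlated with one another at 0.903 to 0.939. Vehicle arrays did so at 0.957 to 0.973 and combination arrays at 0.9 to 0.956. If the dexamethasone arrays spread more than the groups together, the simulated covariance is too small in size. Measured on a dexamethasone array that did not choose the probe sets, the share of the effect reversed was 0.817, 0.68 and 0.52 with replicates 1, 2 and 3 held out, and the mean was 0.672. These used 3, 10 and 333 probe sets, so the smallest share rests on the most. A batch difference can enter these shares too, most plainly with replicate 3 held out, since no vehicle array is in batch C. Within batch C, whose arrays took no part in the choice of 444 probe sets, the median move back was 0.374, against a median dexamethasone effect of 1.68 in batches A and B, which the choice from these arrays inflates. On dexamethasone replicate 3, held out of the choice of the 333, the mean effect was 1.1.

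Under both hormones no probe set differed from vehicle past the threshold. Against vehicle, the combination group differed at 0 of 18625 probe sets by limma; 1139 had an unadjusted p under 0.05, with 931 expected by chance, and the lowest adjusted p was 0.27. With batch as a block 0 passed, and with array weights 5 did. Of the 196 probe sets changed by dexamethasone, the median share of the change still present was 0.349 for those higher and 0.235 for those lower, measured on the arrays that chose them. Absence of a call does not show that a gene had returned to its vehicle level.

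The genes with the lowest unadjusted p were Il15, Ccdc92, Bloc1s2, Aurka and Pigl among those higher, and Ccl2, Gstm4, Pla2g12a, Mfap4 and Rbp7 among those lower, and none of them passed. The muscle cytokine gene Il15 stood at 1.27 ± 0.18 (adjusted p = 0.27), Bloc1s2 at 1.4 ± 0.21 (adjusted p = 0.27), Ccdc92 at 1.12 ± 0.17 (adjusted p = 0.27), Aurka at 1.05 ± 0.18 (adjusted p = 0.467) and Pigl at 1.03 ± 0.19 (adjusted p = 0.581). Ccl2 stood at -1.83 ± 0.25 (adjusted p = 0.27), Mfap4 at -1.89 ± 0.39 (adjusted p = 0.738), Gstm4 at -1.47 ± 0.26 (adjusted p = 0.467), Pla2g12a at -1.43 ± 0.26 (adjusted p = 0.511) and Rbp7 at -0.84 ± 0.18 (adjusted p = 0.738). Of the genes named in advance, Fkbp5 was at 1.43 ± 0.57 (adjusted p = 0.815), Ddit4 at 0.78 ± 0.42 (adjusted p = 0.841), Odc1 at -0.64 ± 0.25 (adjusted p = 0.815) and Klf15 at 0.54 ± 0.24 (adjusted p = 0.815). The others lay between -0.32 (Rcan2) and 0.38 (Ppargc1a), with Trim63 at 0.00 ± 0.35; further probe sets of Nr3c1 and Ppargc1a had the opposite sign (-1 and -0.29), and the 2 others of Igf1 stood at -1.67 and -0.83, beside -0.25.

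At the level of lists, 9 of 28 differed from vehicle by camera at the preset correlation, and 0 with an estimated one or by fry. Extracellular matrix genes had a median of -0.90 (adjusted p = 1.4e-18; adjusted p = 0.42 with an estimated correlation), with 5 that fell over the list alone. It was -0.36 in batch A and -1.13 in batch B. Fibroblast markers had a median of -0.85 (adjusted p = 4e-06, and 0.58 with an estimated correlation), with -0.06 in batch A and -1.19 in batch B. The 8 markers that the matrix list does not hold had a median of -0.45, all below 0. Glucocorticoid receptor targets had a median of 0.31 (adjusted p = 0.00033; adjusted p = 0.32 with an estimated correlation), with 5 that rose over the list alone. Slow fibre genes had a median of -2.08 (adjusted p = 4.7e-08, and 0.58 with an estimated correlation). It was -4.66 in batch A and -0.03 in batch B. Without combination replicate 1 the median was -0.68 (camera adjusted p = 9.6e-06 at the preset correlation, with no estimated one run). Relative to the vehicle mean, the list stood at -0.07 in combination replicate 2 and at -1.26 in replicate 3, a batch C array.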

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

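The comparison of the Gapdh ratio with other hormone-treated arrays was chosen after its values had been seen, while the test on probe sets of the same gene was chosen before its result was known. Probe sets for both ends of control transcripts are outside the comparisons above and draw attention to 2 arrays. The Gapdh 3'/5' signal ratio was 4.94 in dexamethasone replicate 3 and 6.22 in dexamethasone plus testosterone replicate 3, and at most 1.15 in the vehicle arrays. Beta-actin gave 4.73 and 7 in these arrays and at most 2.25 in the vehicle arrays.

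An effect of the hormones on these transcripts is argued against, since the highest Gapdh ratio among the 4 other hormone-treated arrays was 1.17. Shorter labelled cDNA in batch C, from degraded RNA or weak reverse transcription, may account for the ratios. Probe sets of the same gene should then disagree more between batch C and the other batches. Over 2800 genes with several probe sets, their median SD was 0.555 for pairs with batch C and 0.391 for pairs of batches A and B, a ratio of 1.42. The pairs of batches A and B also include vehicle arrays, while those with batch C do not. Greater disagreement is not specific to shorter cDNA, so whether degradation, labelling or another difference of these arrays lay behind it stays open.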

How the results depend on the processing

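The alternatives of batch as a block, without batch C and scaling to a trimmed mean of 500 were chosen after seeing the data; the others were planned. For dexamethasone against vehicle, 196 calls (106 higher, 90 lower) became 23 (22 higher, 1 lower) with values as deposited, 130 (107 higher, 23 lower) with array medians centred, 142 (68 higher, 74 lower) with arrays scaled to 500 and 179 (82 higher, 97 lower) with the batch block. They became 48 with no filter, 469 with a filter at the 60th percentile, 54 with a pseudocount of 1, 414 with a pseudocount 4 times as large as 16, 510 with an intensity trend and robust variance, 123 with only the 2 groups compared, 616 with array weights, 341 with a single probe set per gene and 444 without batch C. For the combination against dexamethasone, 21 calls became 2 (1 higher) as deposited, 6 (3 higher) centred, 0 with no filter, 83 at the 60th percentile, 5 (5 higher, 0 lower) with a pseudocount of 1, 102 with the larger pseudocount, 149 with trend and robust variance, 0 with only 2 groups, 47 with array weights, 73 per gene and 0 without batch C. For the combination against vehicle, 0 became 5 with array weights and stayed 0 in every other setting run. Why these counts moved was not tested.

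The shift of the median of all probe sets with dexamethasone was 0.63 with values as deposited, 0.2 with medians centred and 0.01 after quantile normalization. As deposited, it was -0.26 for the combination against dexamethasone and 0.39 for the combination against vehicle. As deposited, the covariance difference reversed (0.17), as did the oxidative phosphorylation list for the combination against vehicle (0.52); the cause was not tested. The covariance difference moved from -0.10 to -0.06 with no filter and to -0.17 without batch C. The oxidative phosphorylation list also reversed for the combination against dexamethasone without dexamethasone replicate 1 (-0.03; 0.18 without dexamethasone replicate 2, against 0.08 with all arrays), and for the combination against vehicle with arrays scaled to 500 (a median of 0, with camera's direction reversed); the cause was not tested. The cross-fitted share lay between 0.599 and 0.742 over 8 other settings and was not computed with the batch block.

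With each array left out in turn, counts ranged from 1 to 333, 0 to 68 and 0 to 0 in the 3 comparisons. The replicate number as a block gave 13, 0 and 0 calls. The numbers were not taken to pair the animals, since only 5 of 9 same-number pairs deviated together (correlation of deviations above 0.1, range -0.2 to 0.59) and not every array correlated best with its own number. They partly follow the technical batches: number 2 is batch B, and the 0.59 is between the 2 arrays of batch C. Of 33 list calls, 33 passed with the batch block, 28 without batch C, 31 with the replicate block and 2 with an estimated correlation. By fry, 10, 5 and 0 lists passed in the 3 comparisons, against 11, 13 and 9 by camera. The 51 calls of named genes kept their direction in every setting that tested them, which their choice from these arrays largely brings about.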

Other observations

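The tests on slow fibre genes, and the bound set on the planned covariance, were chosen only after the results were seen. Lists not described above give a picture of other cell types and pathways, by camera at the preset correlation. With dexamethasone, endothelial markers had a median log2 change of -0.45 (13 genes, adjusted p = 0.02; adjusted p = 0.27 with an estimated correlation); the list did not pass without vehicle replicate 3 (adjusted p = 0.067). Oxidative phosphorylation genes had a median of -0.18 (57 genes, adjusted p = 0.00048; adjusted p = 0.54 with an estimated correlation). It was -0.45 in batch A and -0.04 in batch B, and the list did not pass without dexamethasone replicate 1 (-0.02, adjusted p = 0.23). Translation factors had a median of 0.19 (33 genes, adjusted p = 0.026; adjusted p = 0.39 with an estimated correlation), and did not pass without dexamethasone replicate 1 or 2 (adjusted p = 0.11 and 0.057). Lists that did not pass were macrophage (-0.47, adjusted p = 0.06), smooth muscle and pericyte (-0.21, 0.06), lymphocyte (0.02, 0.88), adipocyte (0.23, 0.21), Schwann cell (-0.21, 0.53), red blood cell (-0.85, 0.11) and tendon markers (-0.65, 0.11). Neither did glycolysis (0.00, adjusted p = 0.14; fry 0.025), slow fibre (0.33, 0.25), fast fibre (-0.05, 0.11; fry 0.0017), myogenic (0.04, 0.88), denervation (0.29, 0.35), circadian (0.07, 0.88) and inflammation genes (-0.34, 0.11).

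With testosterone added to dexamethasone, adipocyte markers had a median of -0.44 (11 genes, adjusted p = 0.0054; adjusted p = 0.36 with an estimated correlation), and 3 fell when adjusted over the list alone. Without batch C the adjusted p was 0.062. Calls that leaving out single arrays ended were those of autophagy (-0.25, adjusted p = 0.045), oxidative phosphorylation (0.08, 0.039), translation factors (-0.10, 0.029) and amino acid genes (-0.19, 0.03). Their adjusted p were 0.38, 0.81, 0.38 and 0.39 with an estimated correlation. Autophagy did not pass without vehicle replicate 1 or 3, dexamethasone replicate 1 or 2, or combination replicate 1 or 3 (adjusted p up to 0.15). Oxidative phosphorylation did not pass without dexamethasone replicate 1 or 3 or combination replicate 1 or 2 (up to 0.74). Translation factors did not pass without dexamethasone replicate 1 or 2 or combination replicate 3 (up to 0.22), and amino acid genes without dexamethasone replicate 2 or combination replicate 3 (up to 0.34). The calcium-binding fast fibre gene Pvalb stood at -0.92 ± 0.21 with dexamethasone and at 1.04 ± 0.21 with testosterone added (adjusted p = 0.082 and 0.104). Against vehicle, the combination group had lower macrophage (-0.53, adjusted p = 0.0012), endothelial (-0.22, 0.0055), fatty acid oxidation (-0.17, 0.0082), tendon (-0.88, 0.026) and oxidative phosphorylation medians (-0.05, 0.026). With an estimated correlation these adjusted p were 0.58, 0.32, 0.69, 0.58 and 0.73. Macrophage markers did not pass without combination replicate 3 (adjusted p = 0.073), nor fatty acid oxidation without vehicle replicate 1 or combination replicate 1 (0.16 and 0.28), nor tendon markers without vehicle replicate 2 or combination replicate 3 (0.23 and 0.22). Oxidative phosphorylation did not pass without vehicle replicate 1 or 2 or any of the combination arrays (up to 0.11).

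Slow fibre contractile genes were low in dexamethasone plus testosterone replicate 1, where Myl2 and Tnnt1 stood 46.4-fold and 55.2-fold below the vehicle mean. Testosterone lowering them in all 3 animals stays open. In replicate 2 the list median was -0.07 against the vehicle mean and -0.34 against the dexamethasone mean. Against the dexamethasone array of its batch it was -0.58. Without replicate 1 the change from dexamethasone was -0.86 (camera adjusted p = 8.9e-10 at the preset correlation). That p treats genes of the same animals as nearly independent. A piece of muscle with few slow fibres might account for replicate 1. The fast myosin gene Myh4 was not lower there (0.25 above the vehicle mean), while Myh2, of fast oxidative fibres, was 4.01-fold lower. That array's oxidative phosphorylation median of -0.07 and myoglobin at -0.29 speak against a purely white piece. Myoglobin and Myh4 signals were among the highest shown in every array, so their small changes weigh little. A loss of slow fibre transcripts and uneven sampling cannot be told apart, because the part of the muscle taken is not known.

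The move of dexamethasone-changed probe sets back towards vehicle might come from the shared dexamethasone arrays or from batches. The observed covariance lay 0.10 below the simulated mean (difference -0.10). However, the simulated noise was independent between probe sets and of equal spread in all groups. Whether sharing alone could bring about that difference thus stays open. Of 444 probe sets chosen in batches A and B, 72.1% moved back within batch C, where a difference between batches cannot act. Shuffling the signs of the effect 1000 times over probe sets, which are not independent, gave 42.8% to 57.2%. Batch C holds 1 array of each of these groups, so that move cannot be told from a difference between the animals. Nor can it be told from a difference in quality between these arrays, whose Gapdh 3'/5' ratios were 4.94 (dexamethasone) and 6.22 (combination). How much of the effect is reversed stays open: the median move was 0.374, against an effect of 1.68 on the arrays that chose the probe sets, which their choice inflates. Also open, as a hypothesis, is that testosterone counteracts glucocorticoid action in muscle; no testosterone-only group was analysed here, so an independent testosterone effect on the same genes was not tested.

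Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. In 2-group limma fits, the real split of dexamethasone and vehicle gave 123 probe sets and the highest other 0, so that 1 of 10 splits gave as many. For the combination against dexamethasone the real split gave 0 and the highest other 100, so that 10 of 10 gave as many. That other split set combination replicates 1 and 2 and dexamethasone replicate 2 against the rest, with both batch C arrays on the same side. Other splits with both batch C arrays on the same side gave 0, so that feature alone does not account for the 100. For the combination against vehicle, the real split and the highest other both gave 0.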
